A study of Pimephales promelas with 270 samples.

How the data were processed

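The study measured mRNA in larvae of the fathead minnow (Pimephales promelas), a small freshwater fish used in toxicity testing, by sequencing. Larvae of 3 ages (4, 5 and 6 days after fertilization) spent 6, 24 or 48 h in propranolol, a beta-adrenergic receptor blocker, at 0.66 or 3.3 mg/l, or were kept as controls. The 3 ages, 3 durations and 3 doses gave 27 groups, and each combination of age and duration is called an exposure set here. The labels list 270 samples, 10 per group, and the table analysed here holds 266 of them. The other 4, of which 1 belongs to the low dose and 1 to the high dose at 6 days and 24 h and 2 to the controls at 6 days and 48 h, are not analysed here. The treatment text attached to every sample describes an exposure to ethinyl estradiol, whereas the title and design of the series and each sample's dose label describe propranolol. The propranolol labels were used. Whether age was counted at the start or at the end of an exposure is not stated, and neither is whether the samples of a group came from separate vessels, so p-values measure only the spread between these samples, which may be partly technical.

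The values used are whole-number read counts per transcript as the authors deposited them. Per the labels' protocols, larvae were frozen and lysed with a steel bead and libraries were made with the SENSE mRNA-Seq kit V2 (Lexogen). Per the series' design text, reads were mapped to a set of known fathead minnow transcripts. Per the submitters' processing notes, bcl2fastq 2.19.1, limma 3.40.6 and edgeR 3.26.8 were used, with no role given. The aligner, the counting rule and the genome build are not given in the sources used here. The table holds 34856 transcripts, numbered up to 47578, and the lowest total of a transcript over all libraries was 166 counts. Transcripts below some minimum therefore seem to have been left out before deposit. Transcripts of the same gene and near-identical copies can share reads, and how such reads were assigned is not given, so the count of any single transcript is uncertain to that extent.

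The transcripts carry bare identifiers. 0 of them matched the RefSeq gene table, so no gene name is given, and the gene lists and named receptors chosen for this study could not be looked up. Identifiers were printed by a fixed rule that was applied without its requirement of a gene name. It takes the 2 transcripts with the largest rise and the 2 with the largest fall at the high dose, as the mean of the 9 exposure sets, among those with a false discovery rate below 0.05, a mean log2 CPM (CPM, counts scaled to a common library total) of at least 1 and the same sign in at least 8 of 9 sets. 796 transcripts that rose and 357 that fell met these conditions. The rule, the comparisons of each dose with its control and of the doses with each other, the differences between durations and between ages, the 2 comparisons among controls, and a first list of alternatives were fixed before the data were examined. The comparisons for a single duration, the comparison of the 4-day and 6-day sets at 48 h, that of the 6-day, 24 h set with the other 8 sets, and the comparisons between single control groups were added after the data were seen.

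Library totals ran from 5374216 to 30959270 counts (5.37 to 31.0 M counts), with a median of 14.3 M, and 0 libraries fell under 3.56 M, which is 0.25 of the median. Each library had counts above 0 for 32835 to 34779 transcripts, and its 10 most abundant transcripts took 6.95% to 15.8% of the counts. Any pair of libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of at least 4.04 and a median of 15.6, so all were kept as separate samples.

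Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the filterByExpr filter, estimated dispersions and robust quasi-likelihood F-tests. P-values were adjusted by the Benjamini-Hochberg method, and a false discovery rate of 0.05 was the threshold. Within each exposure set the 3 doses were fitted together, because each set has a library code of its own and may have been processed apart. Over all sets, the 27 groups were fitted together with 34000 transcripts, and each dose was compared with the control of its own set before the mean was taken. The 9 control groups were also fitted alone. The standard error of a log2 fold change was its size divided by the square root of F. Levels of single transcripts are TMM-scaled CPM. Log2 CPM used a prior count of 2. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for exact tests, tables and plots.

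The procedure was tested on simulated counts. The changed transcripts were drawn from those with a mean log2 CPM above 1, and group means were otherwise equal. Over the 9 sets, a changed transcript had the same fold in each set. For 1 dose against control within a set (29556 transcripts), 16%, 58%, 88% and 98% of transcripts changed by 1.25, 1.5, 2 and 4-fold were recovered, with 5 false calls among 135. For the mean of the 9 sets (33701 transcripts), 40%, 90%, 98% and 100% were recovered at 1.1, 1.25, 1.5 and 2-fold, with 5 false calls among 169. A change below about 1.5-fold is thus often missed within a single set at this depth and number of samples, even among such transcripts. Less abundant transcripts and changes confined to some of the sets were not simulated, so recovery of these is not known.

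Alternatives were RLE size factors, no filter, DESeq2 1.42.0 (within sets), limma-voom (limma 3.58.1, over all sets and in the controls), sums of libraries with adjacent numbers as the unit of replication, and the replicate number as a block. A limit at 0.25 of the median total removed 0 libraries. Added after the data were seen were fits without 16 libraries that lay far from their group, without each exposure set, without each library in turn for 4 sets, with an apparent age as a covariate, with split controls for overlaps of lists, and without libraries under 9 M counts. A library was called far from its group when the root mean square of its log2 deviations from the group mean, over 14427 transcripts with a mean log2 CPM above 3, exceeded 1.5 times the median of all libraries. The first principal component of the controls was computed on the same 14427 transcripts. Apparent age was the position of a library along the change of the controls with age plus duration, from the 2000 transcripts with the steepest change in the controls of the other 8 sets. Dose labels were also reassigned at random, within a set for 40 splits with the real one included, and in all sets together for 21.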

Results

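Counts per transcript were available for 266 libraries of fathead minnow larvae from 9 exposure sets, which combine an age of 4, 5 or 6 days post fertilization with an exposure of 6, 24 or 48 h. Each set held controls, larvae in 0.66 mg/l propranolol (the low dose) and larvae in 3.3 mg/l (the high dose), with 10 libraries per group except for 9 in each propranolol group of the 6-day, 24 h set and 8 in the controls of the 6-day, 48 h set. Library totals ranged from 5374216 to 30959270 counts, or 5.37 to 31.0 M counts. Group medians lay between 10.23 M, in the low dose of the 4-day, 48 h set, and 17.72 M, in the low dose of the 6-day, 48 h set. The series asks how the response to propranolol varies with the larva's age and with the duration of exposure.

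At the high dose, averaged over the 9 exposure sets, 2233 of 34000 transcripts differed from the controls, of which 1523 rose and 710 fell (edgeR quasi-likelihood test, false discovery rate 0.05). Most of the changes were small. The median size was a log2 fold change of 0.17, or 1.13-fold, and 17 transcripts changed by more than 2-fold. The largest rise by the fixed rule was that of FMt045902, with a log2 fold change of 1.42 ± 0.06 (SE, edgeR adjusted p = 2.6e-58), and its estimate was above 0 in 9 of 9 sets. FMt029894 rose by 1.22 ± 0.19 (SE, edgeR adjusted p = 9.3e-08, above 0 in 8 of 9 sets). The largest falls were those of FMt025853, by a log2 fold change of -1.08 ± 0.28 (SE, edgeR adjusted p = 0.0051), and of FMt025850, by -0.77 ± 0.21 (SE, edgeR adjusted p = 0.0095), each below 0 in 8 of 9 sets. Both falls missed the threshold with limma-voom, at -0.76 (adjusted p = 0.23) and -0.55 (adjusted p = 0.13), and also without the 5-day, 48 h set, at -0.78 (adjusted p = 0.11) and -0.59 (adjusted p = 0.12). The count of changed transcripts was 1448 without the 5-day, 48 h set and 1079 without the 6-day, 48 h set.

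The response to the high dose grew with the duration of exposure. As means of the 3 ages, 8 transcripts differed from control at 6 h (7 rose and 1 fell), 382 at 24 h (349 rose and 33 fell) and 2840 at 48 h (1797 rose and 1043 fell). The median size of the called changes was a log2 fold change of 0.31 at 24 h and 0.30 at 48 h, and 83 transcripts changed by more than 2-fold at 48 h, of which 62 rose. Tested directly, the high-dose effect differed between 48 h and 6 h for 976 transcripts. The difference in log2 fold change was above 0 for 707 and below 0 for 269, and a fall that deepened between 6 and 48 h counts as below 0. FMt045902 did not pass the test at 6 h, at 0.17 ± 0.10 (SE, adjusted p = 0.77), and rose by 1.80 ± 0.11 at 24 h (adjusted p = 6.1e-38) and by 2.29 ± 0.11 at 48 h (adjusted p = 2.6e-50), a 4.90-fold rise. Its difference between 48 h and 6 h was 2.12 ± 0.15 (SE, edgeR adjusted p = 6.9e-29). FMt029894 was at 0.08 ± 0.35 at 6 h (adjusted p = 0.98), at 1.23 ± 0.31 at 24 h (adjusted p = 0.016) and at 2.35 ± 0.32 at 48 h (adjusted p = 8.9e-10), and its difference between 48 h and 6 h was 2.27 ± 0.47 (adjusted p = 0.00043). FMt025853 was at -1.81 ± 0.58 at 48 h (adjusted p = 0.030) and FMt025850 at -1.19 ± 0.38 (adjusted p = 0.031). With limma-voom these were -1.24 (adjusted p = 0.41) and -0.90 (adjusted p = 0.22). Their differences between 48 h and 6 h did not pass the test (adjusted p = 0.41 for FMt025853 and 0.55 for FMt025850). The 8 transcripts at 6 h became 2 with RLE size factors, no filter or limma-voom, 1 with sums of adjacent numbers and 17 without the 16 libraries far from their groups.

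The transcripts that rose at 24 h were largely among those that rose at 48 h. Of the 349 that rose at 24 h, 290 also rose at 48 h, where independent lists of these lengths would share 18.4. Of the 33 that fell at 24 h, 14 also fell at 48 h (1.01 for independent lists), and 0 transcripts were called in opposite directions at the 2 durations. The 2 durations share no library.

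Within single exposure sets, the high dose changed 292 of 29508 transcripts at 4 days and 48 h (252 rose, 40 fell), 365 of 29886 at 5 days and 48 h (283 rose, 82 fell) and 1067 of 30247 at 6 days and 48 h (750 rose, 317 fell). The median log2 fold changes of these calls were 0.54, 0.59 and 0.60, and 39, 53 and 141 of them exceeded 2-fold. At 24 h the counts were 4 at 4 days (3 rose, 1 fell), 24 at 5 days (24 rose) and 205 at 6 days (174 rose, 31 fell). Against the low dose instead of the control, the high dose differed for 284, 1583 and 1214 transcripts at 48 h and for 0, 2 and 368 at 24 h. The 5-day counts thus depended strongly on the group compared. At 6 h edgeR called 0 transcripts at each age, with 3249, 1215 and 1514 at an unadjusted p under 0.05 for 4, 5 and 6 days, and DESeq2 called 80, 0 and 3. The edgeR tests covered 29375, 29571 and 29609 transcripts, of which a share of 0.05 is expected under that p without any effect. DESeq2 also called more than edgeR at 4 days (21 at 24 h and 463 at 48 h), at 5 days (77 and 657) and at 6 days (369 and 1488). Sums of adjacent numbers gave 0 at 4 days and 24 h, 4 and 222 at 5 days (24 and 48 h) and 102 at 6 days and 24 h, the 5-day, 24 h set gave 13 without the libraries far from their groups, and the 6-day, 24 h set gave 76 without its 5 libraries under 9 M counts.

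**Figure D1:**
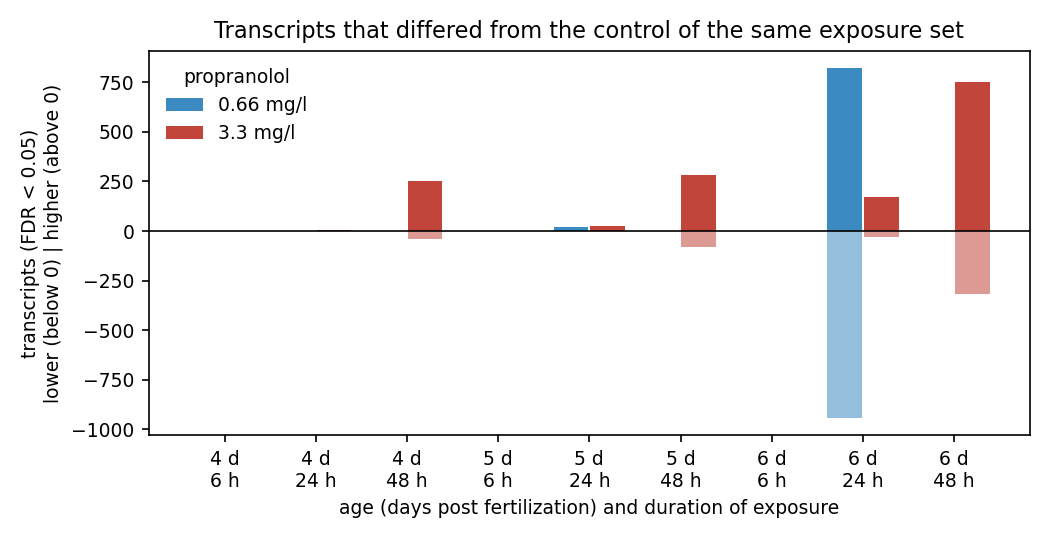
Number of transcripts that differed from the control of the same exposure set (edgeR, false discovery rate 0.05), with higher transcripts above 0 and lower ones below 0, for the low dose in blue and the high dose in red. At the high dose the counts were highest at 48 h for each age, and the low dose had 1763 in the 6-day, 24 h set.

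The 48 h responses of the 3 ages overlapped. The 4-day and 5-day sets shared 73 transcripts that rose (2.42 for independent lists), the 4-day and 6-day sets 134 (6.39) and the 5-day and 6-day sets 179 (7.12). Falls were shared by 4 (0.110), 2 (0.421) and 9 transcripts (0.874) in the same pairs, and 4 transcripts were called in opposite directions at 4 and 6 days. 60 transcripts rose in all 3 sets and 2 fell in all 3. Signs agreed more widely than calls did. Of the transcripts called at 4 days and 48 h, 93.1% had the same sign at 5 days and 48 h and 91.8% at 6 days and 48 h, compared with 71.9%, 48.3% and 63.3% at 6 h (4, 5 and 6 days). Of those called at 6 days and 48 h, 78.9% had the same sign at 4 days and 48 h and 90.3% at 5 days and 48 h, compared with 47.9%, 60.7% and 65.9% at 6 h. Different sets have separate controls. Across the 14427 more abundant transcripts, which are not independent replicates, the high-dose effects at 48 h correlated at r = 0.40 between 4 and 5 days, 0.29 between 4 and 6 days and 0.46 between 5 and 6 days. For the low dose the same pairs gave -0.048, -0.0079 and 0.0024. The low-dose effects of the 5-day sets at 24 and 48 h, however, correlated at 0.52, with 20 and 0 transcripts called. Values of this size can thus arise with few calls, and no chance range was computed.

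FMt045902 shows the time course in single libraries. In the 4-day sets the high-dose larvae had 41.5 ± 9.01 CPM (SD, n = 10) after 6 h, 114 ± 54.8 after 24 h and 250 ± 129 after 48 h, and the controls had 37.0 ± 5.99, 48.1 ± 6.48 and 66.7 ± 16.4 (n = 10 each). In the 6-day sets the high-dose larvae had 104 ± 17.2 CPM after 6 h (n = 10), 666 ± 156 after 24 h (n = 9) and 836 ± 235 after 48 h (n = 10), against 87.8 ± 11.4 (n = 10), 127 ± 18.2 (n = 10) and 133 ± 21.3 (n = 8) in controls. In each 48 h set the lowest high-dose library lay above the highest control library, at 106 against 96.4 CPM for 4 days, 281 against 117 for 5 days and 547 against 174 for 6 days. In the controls themselves this transcript was higher at 6 days than at 4 days by a log2 fold change of 1.22 ± 0.06 (SE, edgeR adjusted p = 2.4e-31). FMt025853 had a far wider spread. Its mean in controls was 238 ± 120 CPM in the 4-day, 6 h set (n = 10) and 1.38 ± 1.43 in the 6-day, 48 h set (n = 8), and it fell in the controls by a log2 fold change of -3.51 ± 0.50 from 4 to 6 days (edgeR adjusted p = 5.0e-09). At 5 days and 48 h it had 0.481 ± 0.215 CPM at the high dose and 5.31 ± 12.7 in controls (n = 10 each), where a single control library reached 41.3 CPM.

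**Figure D2:**
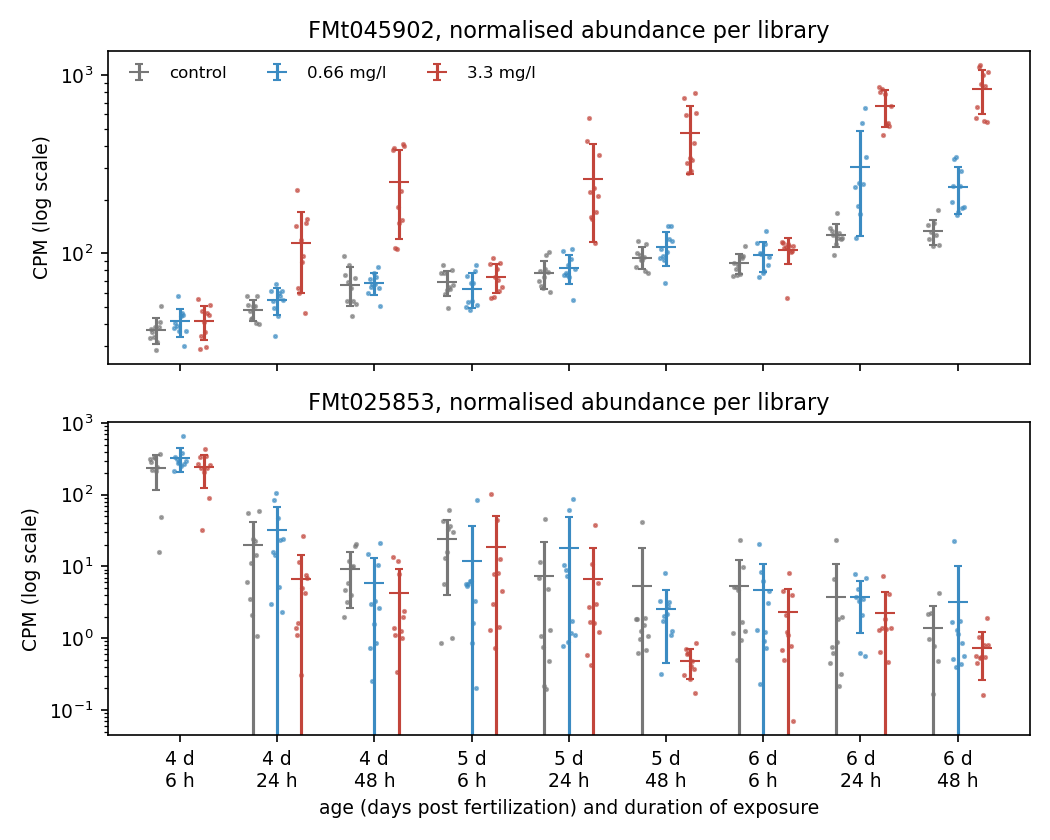
Normalised abundance (CPM, log axis) of FMt045902 and FMt025853 in each library by exposure set, with controls in grey, the low dose in blue and the high dose in red. Bars are the group mean and SD, a lower bar end at or below 0 runs off the log axis, and 1 control library of the 6-day, 48 h set with 0 counts of FMt025853 is not drawn. The high-dose libraries of FMt045902 stand above the controls at 48 h at each age.

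The high-dose effect also differed between the sets of different age. Each set has a library code of its own and libraries serve as replicates. Another difference between sets in the dose effect therefore cannot be told from one of age. The same limit holds for the low dose and for the durations, although the high-dose counts were highest at 48 h for each age. Over the 3 durations it differed between 6 and 4 days for 139 transcripts, with a difference in log2 fold change above 0 for 103 and below 0 for 36 (edgeR, false discovery rate 0.05). FMt045902 was among them, with a difference of 0.65 ± 0.15 (SE, adjusted p = 0.012). FMt029894 (-0.25 ± 0.46, adjusted p = 0.90), FMt025853 (-0.17 ± 0.68, adjusted p = 0.96) and FMt025850 (0.10 ± 0.52, adjusted p = 0.97) did not pass this test. At 48 h alone, 120 transcripts differed between 6 and 4 days, a count that 1 of 20 random reassignments of the dose labels exceeded, with 357.

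The low dose changed far fewer transcripts as a mean of the 9 sets. 94 transcripts differed from control, of which 83 rose and 11 fell, with a median log2 fold change of 0.15. FMt045902 rose by 0.31 ± 0.06 (SE, edgeR adjusted p = 0.0062), which missed the threshold with sums of adjacent numbers (0.31, adjusted p = 0.058), without the 6-day, 24 h set (0.19, adjusted p = 0.63) and without the 6-day, 48 h set (0.24, adjusted p = 0.081). The low-dose values of FMt029894 (-0.31 ± 0.19, adjusted p = 0.57), FMt025853 (0.07 ± 0.25, adjusted p = 0.96) and FMt025850 (0.20 ± 0.21, adjusted p = 0.79) did not pass. The 94 transcripts became 61 with limma-voom, 49 with sums of adjacent numbers and 50 without the libraries far from their groups. Leaving out 1 set gave 0 without the 6-day, 24 h set, 250, 173 and 167 without the 4-day, 24 h, the 5-day, 6 h and the 4-day, 48 h set, and 31 to 58 without any other single set. Compared directly, the 2 doses differed for 2989 transcripts, of which 1684 were higher at the high dose and 1305 lower. This count was 1160 without the 5-day, 48 h set, 1352 without the 6-day, 24 h set and 1136 without the 6-day, 48 h set.

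The highest low-dose count was in the 6-day, 24 h set, where 1763 of 29703 transcripts differed from control, 821 higher and 942 lower. Their median log2 fold change was 0.44, and 84 exceeded 2-fold. The high dose changed 205 transcripts in the same set. Tested directly, the low-dose effect in this set differed from the mean of the other 8 sets for 842 transcripts (1504 without the libraries far from their groups). Of the 1763, 33.1% had the same sign in the high-dose effect at 6 days and 48 h, 35.4% in that at 5 days and 48 h and 42.5% in that at 4 days and 48 h. In the sets of other durations this share was 33.2% to 70.31%, with the highest at 4 days and 6 h. The count rested on several libraries, with 1024 transcripts without control 7, 1033 without control 8, 1092 without low-dose library 17, 883 without low-dose library 19 and 1096 without low-dose library 22. With sums of adjacent numbers it was 459, and with DESeq2 it was 2422. The apparent age of these low-dose larvae differed from that of their controls by -0.308 days (exact permutation p = 0.0095, 0.0647 after adjustment over 18 comparisons), and with apparent age as a covariate 193 transcripts passed, while the median log2 fold change of the 1763 went from 0.44 to 0.36, a ratio of 0.822. FMt045902 had 304 ± 179 CPM in this low-dose group (n = 9) and 127 ± 18.2 in its controls (n = 10).

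In the other sets the low dose changed 20 transcripts at 5 days and 24 h, which rose with a median log2 fold change of 1.12, and 2 at 6 days and 48 h, which rose. The first count was 6 with sums of adjacent numbers and 63 with DESeq2. The second was 0 with those sums, 7 with DESeq2 and 1 without control 2, 4, 7 or 10. The edgeR test called 0 transcripts in the remaining 6 sets. At an unadjusted p under 0.05 it gave 1656 at 4 days and 6 h, 2175 at 4 days and 24 h, 966 at 4 days and 48 h, 723 at 5 days and 6 h, 2445 at 5 days and 48 h and 1004 at 6 days and 6 h. From 29375 to 29886 transcripts were tested in these sets, and a share of 0.05 of them is expected under that p without any effect. DESeq2 called 0, 5, 0, 1, 1 and 0 in these sets. As means of the 3 ages, the low dose changed 0 transcripts at 6 h (1531 at an unadjusted p under 0.05, and 0 with limma-voom), 101 at 24 h (89 rose, 12 fell) and 6 at 48 h (5 rose, 1 fell). Those at 24 h became 55 with RLE size factors and 49 with sums of adjacent numbers, and those at 48 h became 0 with limma-voom. FMt045902 rose at 24 h by 0.51 ± 0.11 (SE, edgeR adjusted p = 0.016) and was at 0.34 ± 0.11 at 48 h (adjusted p = 0.9998). Within single sets at 24 h it was at 0.17 at 4 days (edgeR adjusted p = 0.88), 0.10 at 5 days (0.90) and 1.26 at 6 days (0.0031). Its mean rise at 24 h thus came mainly from the 6-day set. That set also had 1763 low-dose calls, against 0 and 20 at 4 and 5 days, and the 24 h mean was not computed without it. The low-dose effect differed between 48 h and 6 h for 1 transcript, and for 0 with limma-voom, no filter, sums of adjacent numbers or the replicate block and without the libraries far from their groups. It differed between 6 and 4 days for 74, with a difference above 0 for 17 and below 0 for 57. That count was 48 with sums of adjacent numbers, 123 with the replicate block and 254 without the libraries far from their groups. For FMt045902 this difference was 0.62 ± 0.15 (adjusted p = 0.033).

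The low-dose and high-dose effects share their control libraries, so their correlation lies above 0 without any effect. Across 34000 transcripts, which are not independent replicates, the mean effects over 9 sets correlated at r = 0.37, while 100 simulations of unchanged groups with the same controls gave a mean of 0.50 with an SD of 0.0586. The covariance was 0.00317, against a mean of 0.00263 and a highest value of 0.00458 in the simulations, so the difference of 0.000541 from the mean cannot be told from no shared effect. With the controls split so that the 2 effects shared none, r was -0.0516. At 48 h r was 0.34, the simulated mean was 0.53, the covariance was 0.00848 against a simulated mean of 0.00858 (highest 0.0130), and r with split controls was -0.132.

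Transcript levels in the controls changed widely with age and with time in the experiment. Of 32555 transcripts, 17135 differed between 6 and 4 days, 8667 higher and 8468 lower at 6 days, with a median log2 fold change of 0.42, and 1690 exceeded 2-fold, of which 1380 were higher at 6 days. Between 48 and 6 h, 10933 differed, 5522 higher and 5411 lower at 48 h, with a median of 0.36. The 2 lists overlapped by direction, with 3812 transcripts higher in both (1470 for independent lists), 3404 lower in both (1407) and 283 and 319 in opposite directions (1441 and 1436), although the 2 comparisons use the same control libraries. With the controls split so that the lists shared none, 3114 and 2186 were higher in both (845 and 851 for independent lists) and 2227 and 1400 lower in both (602 and 606). FMt029894 was lower at 6 than at 4 days by a log2 fold change of -1.51 ± 0.39 (SE, edgeR adjusted p = 0.00068), and FMt025850 by -3.10 ± 0.41 (edgeR adjusted p = 6.8e-10). FMt045902 was higher at 48 h than at 6 h by 0.64 ± 0.06 (edgeR adjusted p = 3.0e-15). Each combination of age and duration has a library code of its own, so that differences between control groups and any difference in library processing cannot be told apart.

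Control larvae were ordered by age plus duration. The first principal component of the control libraries took 37.6% of the variance, and its group means rose from -58.9 ± 4.39 (SD, n = 10) at 4 days and 6 h to 43.0 ± 5.38 (n = 8) at 6 days and 48 h. Over the 9 control groups the component correlated with age plus duration at Pearson's r = 0.97 and Spearman's rho = 0.99, with an exact permutation p of 2.2e-05 for each (2-sided, 362880 pairings, 2.2e-05 after adjustment over the 2), the smallest that the pairings can give with these ties. Without the 2 groups farthest from the median day, r was 0.96 (exact permutation p = 0.00079, 7 groups). The step from 24 to 48 h was 32.2 at 4 days, 16.2 at 5 days and 5.02 at 6 days, while that from 6 to 24 h was 23.0, 24.2 and 23.5. Groups with the same age plus duration still differed. Between the 5-day, 24 h and the 4-day, 48 h controls 9145 transcripts differed, and between the 6-day, 24 h and the 5-day, 48 h controls 5030. Controls of the same duration and 1 day apart in age differed for 10091 transcripts (5 against 4 days, 24 h) and 6938 (6 against 5 days, 24 h).

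**Figure D3:**
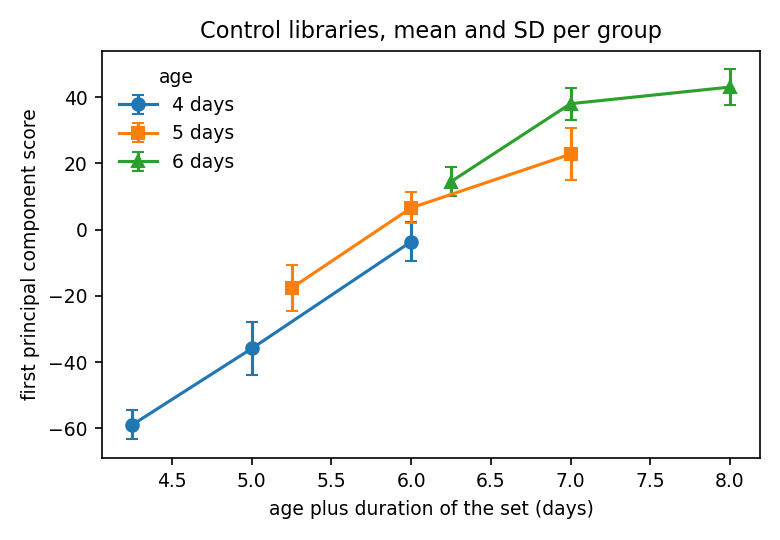
First principal component score (mean and SD of the control libraries of each exposure set, n = 8 to 10) against age plus duration in days, with 1 line per age. The means rise from -58.9 to 43.0.

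Many transcripts that the high dose changed at 48 h also differed between 6-day and 4-day controls. Of 1779 that rose and were tested in both, 1000 were also higher at 6 than at 4 days in controls (474 for independent lists) and 254 were lower (463). Of 1037 that fell, 611 were lower at 6 days in controls (270) and 146 were higher (276). The 48 h controls enter both comparisons. In 5 simulations of unchanged high-dose groups against these controls 0 transcripts were called at the high dose, so that list was empty and the simulations say nothing about an overlap made by the shared controls. With the controls split by position so that the lists shared none, 962 and 350 transcripts rose and were higher at 6 days (383 and 166 for independent lists), while 130 and 134 rose and were lower. For the falls the 2 splits disagreed. 657 and 92 fell and were lower at 6 days (213 and 70.8), while 67 and 156 fell and were higher (251 and 76.4), so the direction of this overlap depended on the controls used. Apparent age at the high dose after 48 h differed from that of controls by 0.299 days at 4 days (exact permutation p = 0.0036, 0.0645 adjusted over 18 comparisons), 0.230 days at 5 days (p = 0.011, 0.0647 adjusted) and -0.0605 days at 6 days (p = 0.58, 0.780 adjusted). With it as a covariate the counts of changed transcripts were 73 at 4 days, 175 at 5 days and 1466 at 6 days, and the median log2 fold change of the calls was 0.849, 0.883 and 1.01 of its value without it. Apparent age did not resolve stage at 6 days and 48 h, where the controls had 7.14 days against 7.33 in those of the 6-day, 24 h set. The high-dose mean there was pulled down by library 37, with 6.52 days against 7.01 to 7.24 in the others. FMt045902 rose in both comparisons, while FMt029894 rose with the dose and was lower at 6 than at 4 days in controls. FMt025853 and FMt025850 fell in both.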

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

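The overlap with split controls, the comparisons of apparent age, the fits with it as a covariate, the fits without shallow libraries or without libraries far from their groups, the correlation with the 48 h high-dose effect, the tests on the far libraries, and the 48 h age difference and the comparison of the 6-day, 24 h set with the others were chosen only after the result was seen.

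The difference of the high-dose effect between 48 and 6 h was tested directly between groups, with 976 transcripts, and so was that between 6 and 4 days, with 139. For FMt045902 these differences were 2.12 and 0.65 on the log2 scale, and for FMt029894 the first was 2.27. The low-dose effect differed between 6 and 4 days for 74 transcripts, with 0.62 for FMt045902, and between 48 and 6 h for 1. At 48 h alone the high-dose effect differed between 6 and 4 days for 120 transcripts. The low-dose effect of the 6-day, 24 h set differed from the mean of the other 8 sets for 842.

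Random reassignment of the dose labels within each set gave 40 splits per set, the real one included. For the high dose at 4 days and 24 h the real count of 4 was above that of each other split (highest 0), and the same held for 292 at 4 days and 48 h (highest 3), 24 at 5 days and 24 h (0), 365 at 5 days and 48 h (0), 205 at 6 days and 24 h (0) and 1067 at 6 days and 48 h (1). It also held for the low dose with 20 at 5 days and 24 h (2), 1763 at 6 days and 24 h (1) and 2 at 6 days and 48 h (0). In these 9 comparisons 1 of 40 splits, the real one, gave as many. That is the smallest share 40 splits can give, and it was not adjusted over the comparisons. A random split is thus an unlikely source of the counts of 20 or more. Chance cannot be excluded for the counts of 4 and 2, which were 0 with sums of adjacent numbers. The splits treat libraries as independent, so they say nothing about a difference between vessels. In the other 9 comparisons, where the real count was 0, all 40 splits gave as many. There the highest other counts were 1, 0 and 0 for the high dose at 6 h (4, 5 and 6 days), and for the low dose 6, 2 and 0 at 4 days (6, 24 and 48 h), 0 and 1 at 5 days (6 and 48 h) and 1 at 6 days and 6 h.

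Over all sets together 21 splits were used. For several comparisons the real count was above that of each other split, which is 1 of 21 splits, unadjusted over the comparisons. These were the high dose as the mean of 9 sets (2233, highest other 4), the low dose (94, 2) and the difference of the doses (2989, 3). The high-dose differences between 48 and 6 h (976, 3) and between 6 and 4 days (139, 3) were also among them. So were the high dose at 24 h (382, 5) and at 48 h (2840, 57). For the low dose they were the difference between 6 and 4 days (74, 12), 24 h (101, 5) and the 6-day, 24 h set against the others (842, 4). Chance cannot be excluded for the high dose at 6 h, where 2 of the 21 splits gave at least the real 8 (highest other 10), the low dose at 6 h, where 21 splits gave at least 0 (6), the low dose at 48 h, where 3 splits gave at least 6 (9), and the low-dose difference between 48 and 6 h, where 6 splits gave at least 1 (4). For the 48 h age difference of the high dose, 2 splits gave at least 120, and the other of them gave 357, so chance cannot be excluded there. The source of the 357 calls was not tested. Among the controls the real count was likewise above each other split for 6 against 4 days (17135, highest other 1414) and 48 against 6 h (10933, 10). The same held for 5 days and 24 h against 4 days and 48 h (9145, 3516) and 6 days and 24 h against 5 days and 48 h (5030, 9). It also held for the pairs 1 day apart (10091, 6, and 6938, 4). These splits reassigned the libraries of all 9 control groups, which differ in age and duration. The random splits with 1414 and 3516 calls may hold an uneven mix of these, which was not tested.

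The first pattern weighed was the 1763 transcripts of the low dose at 6 days and 24 h, more than the high dose changed in that set. The low-dose larvae had an apparent age 0.308 days below that of their controls (exact permutation p = 0.0095, 0.0647 after adjustment over 18 comparisons), which leaves a shift of stage open. With apparent age as a covariate, the median log2 fold change of the 1763 went from 0.44 to 0.36, a ratio of 0.822. By least squares on log2 CPM it was 0.817, and 0.795 to 0.846 without any single library. In that fit 193 transcripts passed, because the fold was smaller and the median SE rose from 0.11 to 0.12. Apparent age as measured thus took up a small part of the fold. It is imprecise, since controls with the same age plus duration had 6.80 days (5-day, 48 h) and 7.33 days (this set). An imprecise covariate corrects too little, so a stage difference as the whole source stays open. Shallow libraries are argued against as the source by the fit without 5 libraries under 9 M counts, where the ratio was 1.03 and 1202 transcripts passed, 1077 of them among the 1763. A low-dose response of the kind seen at the high dose cannot be told from chance, since the correlation with the 48 h high-dose effect was -0.246, within the range of -0.253 to 0.252 from reassigned labels, so a response particular to this set may remain, as an untested explanation.

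The second pattern was the response to the high dose at 48 h, many of whose transcripts also differed between older and younger controls. The correlation of that response with the change per day in controls passed in no set (permutation p = 0.378 or higher, adjusted). Apparent age exceeded that of controls by 0.299 days at 4 days (exact permutation p = 0.0036, 0.0645 adjusted) and 0.230 days at 5 days (p = 0.011, 0.0647 adjusted), and differed by -0.0605 days at 6 days (exact permutation p = 0.780 adjusted), so no shift of stage passed the correction and one stays open for each set, also at 6 days, where the controls had 7.14 days against 7.33 in those at 24 h and the measure did not resolve stage. With apparent age as a covariate the median log2 fold change of the called transcripts was 0.849 of its value at 4 days and 0.883 at 5 days. By least squares on log2 CPM these were 0.842 (0.824 to 0.880 without any single library) and 0.890 (0.845 to 0.922). Apparent age as measured thus took up a small part of the fold in these 2 sets. It is imprecise, since controls with the same age plus duration had 6.80 days (5-day, 48 h) and 7.33 days (6-day, 24 h). An imprecise covariate corrects too little, so a stage difference as the whole source stays open. The 1.01 at 6 days (1.01, and 1.00 to 1.02) cannot tell either, because the measure did not resolve stage there. The calls were 73 and 175 in the first 2 sets, because the folds went from 0.54 to 0.46 and from 0.59 to 0.53 while the median SE rose from 0.11 to 0.13 and from 0.12 to 0.13. Libraries far from their groups are argued against by 2808 calls without them. An effect of the exposure other than a shift of stage may account for part of the change at 4 and 5 days. That is a hypothesis found on the same data, and apparent age cannot decide it.

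The third pattern was that 16 libraries lay far from their groups, 11 of them among the 90 of the 5-day sets (Fisher's exact test against the other ages, p = 0.0046), and that 34.5% of the pairs of them from different groups had deviations correlated above 0.5, against 0.0864% of pairs of other libraries. A depth lower or higher in all of them is argued against, since their totals differed from those of their groups by -0.0784 on the log2 scale on average (permutation p = 0.29). That mean cannot exclude depth for single libraries. High-dose library 43 at 5 days and 48 h had the lowest total of its group, 6.65 M, and 32835 transcripts detected. Low-dose library 23 at 5 days and 6 h (33570) and control 14 at 5 days and 48 h (33796) were also lowest in detection, which was not tested over the far libraries. The 10 most abundant transcripts took at most 15.8% of the counts in any library, so they did not take most of them. Their share was still 1.16 percentage points higher in the far libraries (permutation p = 3.0e-05), so a part played by abundant transcripts stays open. Dose as the sole source is argued against, since 8 of them were controls, 3 had the low dose and 5 the high dose (Fisher's exact test, p = 0.255). A shift common to a whole set is removed with the group mean. Age, which the design names, could thus act only through a wider spread within groups, and this stays open. The same holds for a difference in processing of the 5-day sets, which the library codes could carry. A cause confined to the 5-day sets would not cover the far libraries of the other ages.

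The remaining items are single libraries whose gap to the nearest other library, as a share of the group's range, exceeded Dixon's limit. In 108 tests (27 groups and 4 measures), 5.4 such cases come by chance, and 13 were seen. For library totals they were the high dose at 4 days and 24 h, library 34, with 31.0 M counts (gap 0.737), the high dose at 5 days and 48 h, library 43, with 6.65 M (0.613), and the controls at 6 days and 6 h, library 11, with 9.46 M (0.508). For transcripts detected they were the low dose at 5 days and 6 h, library 23, with 33570 (0.713), the low dose at 5 days and 24 h, library 29, with 34685 (0.587), the controls at 5 days and 48 h, library 14, with 33796 (0.539), the high dose at 5 days and 48 h, library 43, with 32835 (0.945), and the high dose at 6 days and 24 h, library 37, with 33271 (0.596). For FMt045902 the high-dose library 37 at 6 days and 6 h was low, with a log2 CPM of 5.82 against 6.67 to 6.85 in the others (0.824). That library also had an apparent age of 5.33 days against 6.36 to 6.91 in the others of its group. Library 34 of the high dose at 4 days and 24 h had 6.11 days against 4.54 to 5.29. Apparent age was not among the 4 measures, and the source of these 2 values was not tested. FMt025853 was high in the low dose at 4 days and 6 h, library 26 (9.35, gap 0.475), the low dose at 5 days and 6 h, library 29 (6.38, gap 0.468), the controls at 5 days and 48 h, library 8 (5.37, gap 0.753), and the low dose at 6 days and 48 h, library 19 (4.53, gap 0.665).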

How the results depend on the processing

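The fits with apparent age, without shallow or far libraries, without a set and without each library were chosen after the results were seen, as was each comparison named in the processing account as added. Of 398 counts, shares and correlations under an alternative, 323 stayed within the limits (1.5 times for a count) and 75 did not. This total mixes unlike alternatives, among them fits without each library in turn, which reuse most of the same data. Comparisons in which neither fit called a transcript also count as within the limits. By alternative, 6 of 18 values stayed within them with DESeq2 and 19 of 33 with sums of adjacent numbers. With limma-voom 17 of 21 did, with RLE size factors 36 of 39 and with no filter 37 of 39. Of 196 values of the printed transcripts, 187 kept their direction and their side of the threshold. The other 9 are given in the text of the comparisons. Except where stated, the cause of a change was not tested. Gene lists and sums over gene symbols were not run because no transcript carries a symbol.

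DESeq2 gave, for the high dose, 80 at 4 days and 6 h, 21 and 463 at 24 and 48 h, 77 and 657 at 5 days (24 and 48 h), and 3 and 369 at 6 days (6 and 24 h). For the low dose it gave 5 at 4 days and 24 h, 1, 63 and 1 at 5 days (6, 24 and 48 h) and 7 at 6 days and 48 h. Sums of adjacent numbers, with fewer units per group, gave for the high dose 2 and 0 at 4 days (6 and 24 h), 4 and 222 at 5 days (24 and 48 h) and 102 at 6 days and 24 h. For the low dose they gave 6 and 1 at 5 days (24 and 48 h), 459 and 0 at 6 days (24 and 48 h), 49 for the mean of sets, 49 at 24 h, 0 for 48 against 6 h and 48 for 6 against 4 days, and for the high dose at 6 h 1.

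RLE size factors gave 1 for the low dose at 4 days and 24 h, 2 for the high dose at 6 h and 55 for the low dose at 24 h. No filter gave 0 for the low-dose difference of 48 and 6 h and 2 for the high dose at 6 h. Limma-voom gave 61 for the low dose as a mean of sets, 0 for its difference of 48 and 6 h, 0 at 48 h, and 2 for the high dose at 6 h. Without far libraries there were 13 for the high dose at 5 days and 24 h, 17 for it at 6 h, 50 for the low dose as a mean, 0 for its difference of 48 and 6 h, 254 for that of 6 and 4 days and 1504 for the 6-day, 24 h set against the others.

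With apparent age as a covariate the 48 h high-dose counts were 73 at 4 days, 175 at 5 days and 1466 at 6 days (within the limit), and the low-dose count at 6 days and 24 h was 193. Without libraries under 9 M counts the high dose at 6 days and 24 h gave 76, with fewer samples. Leaving out each control or high-dose library gave 235 to 328, 252 to 372 and 801 to 1260 for the high dose at 48 h (4, 5 and 6 days) and 144 to 216 at 6 days and 24 h. Low-dose libraries are fitted together with these groups, and without one of them the counts reached 453 at 5 days and 48 h (library 25) and 227 at 6 days and 24 h (library 28). For the low dose, leaving out each control or low-dose library gave 883 to 2158 at 6 days and 24 h (1024, 1033, 1092, 883 and 1096 without controls 7 and 8 and low-dose libraries 17, 19 and 22) and 1 to 3 at 6 days and 48 h (1 without control 2, 4, 7 or 10).

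Without the 5-day and without the 6-day, 48 h set, the high dose as a mean gave 1448 and 1079. The doses differed for 1160, 1352 and 1136 transcripts without the 5-day, 48 h, the 6-day, 24 h and the 6-day, 48 h set. The low dose as a mean gave 58, 250 and 167 without the 4-day sets (6, 24 and 48 h), 173, 42 and 31 without the 5-day sets and 52, 0 and 35 without the 6-day sets. The correlation of the doses reversed with split controls, to -0.0516 and, at 48 h, -0.132, because the shared controls were removed, and was 0.289 and 0.276 for transcripts with a log2 CPM of at least 3. Of the transcripts that fell at the high dose at 48 h and differed with age in controls, 80.7% were lower at 6 days. With split controls this share was 90.7% and 37.1%, so it reversed in 1 of the 2 splits, where different controls were used.

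Replicate numbers are shared by groups of the same dose in different sets and not within a set, so no paired analysis was possible because the groups compared share no number for the dose comparisons within sets. The numbers did not pair the libraries. Deviations of libraries with the same number correlated at 0.00523 on average, and other numbers at 0.00115, with a lowest pair of -0.562, and 12.4% of libraries correlated best with their own number (10% by chance). With the replicate block, the high-dose differences gave 960 (48 against 6 h) and 108 (6 against 4 days), the low-dose ones 0 and 123, and the controls 17097 (age) and 10754 (duration).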

Other observations

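The comparison of high-dose responses between 24 h and 48 h within the 6-day larvae was chosen after the results were seen. There, 124 transcripts rose in both sets, where independent lists would share 4.40, and the 2 sets have no library in common. Of the 205 transcripts called at 6 days and 24 h, 94.6% had the same sign at 6 days and 48 h, 93.1% at 5 days and 48 h and 83.9% at 4 days and 48 h. The median log2 fold change in the same direction was 0.58 at 6 days and 48 h, against 0.56 in the set where they were called.

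Transcripts that rose at the low dose at 24 h, as the mean of the 3 ages, were compared with the high-dose response at 48 h. Of 89 that rose, 14 also rose at the high dose at 48 h (4.70 for independent lists) and 4 fell (2.73). Of the 12 that fell, 0 were called at the high dose at 48 h in either direction. No library entered both lists.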
